A study of Mus musculus with 4 samples.

How the data were processed

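CD45+ cells sorted by fluorescence-activated cell sorting from 2153L tumours were profiled by droplet-based 10x 3' single-cell RNA sequencing in 4 libraries. 2153L is a mouse mammary tumour line from a genetically engineered model, grown here by transplantation into the mammary fat pad of female Balb/c mice. The groups were vehicle, ORIN1001 at 150 mg/kg, docetaxel at 20 mg/kg, and the combination of both drugs at these doses, each given for 8 days. Each group held 1 library, and the number of mice behind a library was not given in the sources used here.

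The deposited matrices held raw UMI counts per gene and cell barcode for barcodes that Cell Ranger 5.0.1, per the file headers, had called as cells. Per the submitters' processing notes, reads were processed with Cell Ranger against mm10, and Seurat 4.0.1 was used downstream. No normalization had been applied to the deposited counts. The annotation release behind the 32285 features was not given in the sources used here, and 40 duplicated gene symbols were made unique. Gene coordinates were looked up by Ensembl identifier in GENCODE release M21 for mm10.

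Barcodes with at least 200 detected genes and under 10% mitochondrial UMIs passed the filter: 10239 in vehicle, 8760 in ORIN1001, 8343 in docetaxel and 8945 in the combination. Doublets were scored per library with Scrublet in scanpy 1.11.5. Its automatic threshold marked 2.00% of the vehicle library, 0% of ORIN1001, 1.27% of docetaxel and 1.82% of the combination. Where it marked under 0.5%, which was so for ORIN1001, the top-scoring cells at 0.8% per 1000 cells were removed instead, so 7.01% of that library was removed. Cells kept were 10034, 8146, 8237 and 8782 in the same order, with median UMIs of 4134, 4083, 3854 and 4436.5 and median detected genes of 1602, 1483, 1624 and 1895.5.

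Kept cells of all 4 libraries were normalized to 10000 UMIs, log-transformed and clustered together on 2000 variable genes chosen per library. Scaled values were limited to 10, and 30 principal components, 15 neighbours and Leiden clustering at resolution 1 with seed 0 were used, without batch integration. Clusters were named from fixed marker sets of 16 cell types by the highest mean of marker expression standardized across clusters, with at least 3 markers detected in 10% of a cluster's cells; a cluster far below its libraries' median depth with none of its own markers among its leading genes stayed unnamed. T cell-like and NK cell-like clusters were clustered again and named from markers of 6 subsets, with a stricter rule set after seeing the subclusters: the first marker of a set had to reach 25% of its highest subcluster value, and subclusters holding both Cd4 and Cd8a at that level, or led by markers of another lineage, stayed unnamed. The limits on detection and depth were set with the data in hand. Conventional DC subtypes were merged, as were B and plasma cells. A class name ending in "-like" means this marker-based name and no more.

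UMIs were summed per library and class, and expression is given in CPM, the counts of a gene per 1e6 counts of that sum, computed here from the deposited counts. For each gene and each pair of libraries, the log2 ratio of CPM was computed with an exact 95% interval for the ratio of 2 Poisson counts. Shares of cells carry exact Clopper-Pearson 95% intervals, and a share of 0 the limit of 3 counts of the total. A count of 0 was set to 3 counts for a ratio. All intervals cover counting error only. Because there was 1 library per group, no test across samples was run, no p-value is given and no gene was called changed.

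The contrasts were ORIN1001 to vehicle, docetaxel to vehicle, combination to vehicle and combination to docetaxel. Combination to ORIN1001 was computed for the correlations across genes and for effects of 1 drug with and without the other. The marker sets, the 20 gene lists, the contrasts, the rule for named genes and most alternatives were fixed before the data were examined. For a list, the median log2 ratio of its members with at least 10 UMIs in either library is given. Its percentile among 10000 random lists of the same size, each member drawn from the nearest 50 genes in mean expression, describes these libraries only. Mx1 and Mx2 were not among the features, so 18 members of the type I interferon list were used. Cd274, Ccl3, Ccl4, Ccl5 and Il1b each belong to more than 1 list.

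Genes were named in the 3 immune classes with the most cells and at least 200 cells in every library. In each class and contrast the rule took the 5 largest positive and 5 largest negative log2 ratios. Eligible genes had at least 30 UMIs and 50 CPM in the higher library, intervals that did not overlap, and a mean CPM of at least 5% of that in the class where the gene was highest. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin, T cell receptor and predicted genes were left out. From each list up to 4 members with the largest absolute ratios and at least 30 UMIs were added, and these could lie under the 5% limit.

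The gene ratios were tested on simulated data for the combination and vehicle libraries, with 200 genes of known ratio per class; a gene counted as recovered when it met the limits of 30 UMIs, 50 CPM and intervals that did not overlap, with the right direction. In neutrophil-like cells 100% of the genes simulated at 2, 4, 0.5 and 0.25 of their level were recovered. In macrophage-like cells 98% were recovered at 0.5, and in T cell-like cells 96% were recovered at 0.5 and at 0.25, with 100% at the other ratios. Of the unchanged genes, 0 of 2507, 0 of 2730 and 0 of 3216 reached a 2-fold ratio and met the same limits in the 3 classes. The intervals covered the simulated ratio for 95.7%, 94.9% and 95.6% of the unchanged genes. Both libraries were drawn as Poisson counts from 1 shared profile per class. These values therefore cover counting error only and say nothing about differences between animals or tumours.

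Alternatives planned for the shares were at least 500 detected genes, under 5% mitochondrial UMIs, no doublet removal, Leiden resolution 0.5 and 2, and classes taken per cell from the highest marker mean. Alternatives planned for the genes and lists were TMM factors from edgeR 4.0.16, the mean of each cell's CPM, cells thinned to 1000 UMIs, no doublet removal, at least 500 detected genes, and list members with at least 50 UMIs. Correlations across genes used genes with a mean of at least 50 CPM. Their alternatives were 200 CPM, and leaving out mitochondrial, ribosomal protein and dissociation stress genes. One doublet rate for every library and a joined macrophage and monocyte class were added after seeing the data. Values were computed with Python 3.11.15, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and R 4.3.3.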

Results

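Single-cell RNA profiles were collected from CD45+ sorted cells of 2153L mammary tumours after 8 days of treatment, in 4 libraries that each stood for 1 group. The groups were vehicle, the drug ORIN1001, the drug docetaxel, and both drugs together, called the combination. ORIN1001 inhibits the RNase activity of IRE1α, the endoplasmic reticulum stress sensor that splices Xbp1 mRNA. Docetaxel is a taxane that stabilises microtubules. The libraries held 10362 barcodes and 86383509 UMIs for vehicle, 8839 barcodes and 64257802 UMIs for ORIN1001, 8464 barcodes and 78746915 UMIs for docetaxel, and 9109 barcodes and 81375538 UMIs for the combination. There were no replicates, so every difference given here is between single libraries, no spread between animals was measured, and the 95% intervals in brackets cover counting error only.

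Most kept cells were neutrophil-like, macrophage-like or T cell-like by their markers. Monocyte-like, NK cell-like, B or plasma cell-like, mast cell-like and several dendritic cell-like classes made up nearly all of the rest. Cells had been sorted for CD45, so shares describe sorted leukocytes and not the tumour. Barcodes in the files began at 500 to 503 UMIs, a floor that falls hardest on classes with little RNA, and neutrophil-like cells had median UMIs of 2925 in vehicle, 3446 in ORIN1001, 2529 in docetaxel and 2192.5 in the combination. Epithelial or tumour cell-like cells passed the sort at 1.47% of kept cells in vehicle, 0.368% in ORIN1001, 0.473% in docetaxel and 1.23% in the combination. No cluster was named as fibroblasts, endothelial or erythroid cells, and 0 of 10034 vehicle cells in such a cluster allows a share of up to 0.0299% at 3 counts. Names were given to whole clusters, so this does not limit such cells that fell in other clusters. Mast cell or basophil-like cells numbered 2 in vehicle, 0 in ORIN1001, 2 in docetaxel and 7 in the combination.

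**Figure D1:**
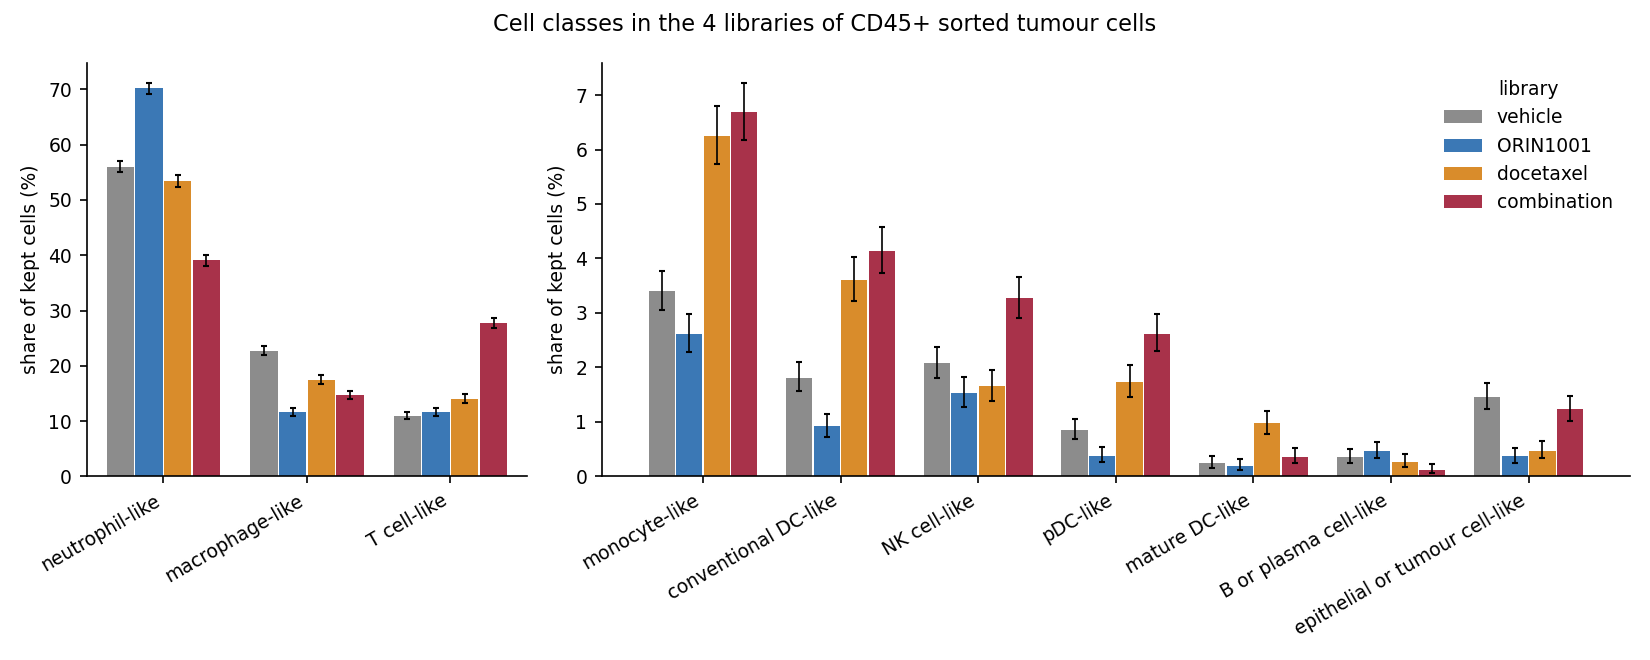
Share of kept cells (%) in each cell class for the 4 libraries, with exact 95% binomial intervals as error bars and 1 bar per library. The neutrophil-like bar is highest with ORIN1001 at 70.2% and lowest with the combination at 39.1%, and the T cell-like bar of the combination stands at 27.7% against 10.99% in vehicle.

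The comparison of ORIN1001 with vehicle asked what the IRE1α RNase inhibitor alone went with. The ORIN1001 library held more neutrophil-like and fewer macrophage-like cells, and both classes carried higher interferon-γ-response genes. Gbp4, an interferon-inducible GTPase, stood at 73.4 CPM in neutrophil-like cells against 11.05 CPM in vehicle, a log2 ratio of 2.73 (2.53 to 2.94). Cxcl9, a chemokine that attracts T cells through CXCR3, stood at 166 CPM in macrophage-like cells against 20.8 CPM, a log2 ratio of 2.99 (2.88 to 3.10). Genes of the XBP1s and endoplasmic reticulum chaperone list were lower in neutrophil-like cells, all 18 of them. In T cell-like cells the inhibitory receptor genes Lag3 and Havcr2 and the perforin gene Prf1 were higher.

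Neutrophil-like cells were 70.2% (69.2 to 71.2) of kept cells with ORIN1001 and 56.0% (55.0 to 57.0) in vehicle, a log2 share ratio of 0.33 (0.27 to 0.38). Macrophage-like cells were 11.6% (10.96 to 12.4) against 22.8% (21.9 to 23.6), a log2 share ratio of -0.97 (-1.08 to -0.86). The joined macrophage and monocyte class, chosen after its values were seen, was 14.3% against 26.2%. Conventional DC-like cells were 0.921% against 1.81%, and pDC-like cells 0.381% against 0.847%. Outside the neutrophil-like class the macrophage-like, conventional DC-like and pDC-like shares were also lower, but by a smaller factor. T cell-like cells were 11.6% against 10.99%, a difference within counting error, but 39.1% against 24.99% of the cells outside the neutrophil-like class. The monocyte-like share was lower at 2.61% against 3.40%, and turned higher when classes were taken per cell from marker means, with a log2 share ratio of 0.22.

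In neutrophil-like cells all 15 members of the interferon-γ and MHC class I list were higher with ORIN1001, with a median log2 ratio of 1.16 at percentile 100 of the random lists, and from 0.37 to 1.47 within single neutrophil-like clusters. Examples besides Gbp4 were Nlrc5, the activator of MHC class I genes, at 1.996 (1.79 to 2.21), Gbp2 at 1.65 (1.60 to 1.70) and Irf1 at 1.304 (1.26 to 1.35). All 18 measured type I interferon genes were higher as well, with a median of 0.49, but within cluster 10, which held 624 and 294 of the cells, 12 of 18 were lower and the median was -0.48. In the other 6 neutrophil-like clusters the median lay between 0.15 and 0.58. Clusters were drawn from the same expression values. Cluster 9, whose leading genes included Ifit1, Ifit2 and Rsad2, held 285 ORIN1001 and 163 vehicle cells. A median within cluster 10 therefore leaves out cells high enough in these genes to fall in cluster 9. The dsRNA sensing and pyroptosis list had 9 of 14 members higher, a median of 0.31, and Zbp1, a sensor of nucleic acids, at 1.28. Il18bp, which encodes a decoy for interleukin 18, stood at 127 CPM against 36.9 CPM. The 18 XBP1s and chaperone genes, with a median of -0.43 at percentile 0, included Manf at -0.82 (-0.95 to -0.70), Hsp90b1 at -0.81 (-0.90 to -0.72) and Sdf2l1 at -0.91 (-1.20 to -0.63). RIDD substrates, which are mRNAs that the IRE1α RNase degrades, had 4 of 5 members lower and a median of -0.15 at percentile 30.6, within the random range. PERK-ATF4 genes, from another branch of the unfolded protein response, had 9 of 10 members lower and a median of -0.12 at percentile 17.6, also within it.

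Other genes were lower in the same neutrophil-like cells. Nr4a1, an immediate early gene, stood at 349 CPM against 785 CPM, a log2 ratio of -1.17 (-1.21 to -1.13). Monocyte and neutrophil chemokines had 12 of 13 members lower and a median of -0.75, with Ccl3 at -0.75 and Ccl4 at -0.76. Ptgs2, the inducible cyclooxygenase of the inflammatory list, was at -0.74, and the list's median was -0.27. MHC class II genes had a median of -0.90, proliferation genes -0.73 and lipid-associated macrophage genes -0.17, and the macrophage markers in these cells were also lower, with a median of -1.14. These MHC class II genes stood at about 1% of their level in the class where they were highest. Tubulins had 7 of 8 members lower and a median of -0.31, and p53 targets 7 of 8 lower and a median of -0.33.

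Macrophage-like cells had 14 of 15 interferon-γ and MHC class I genes higher with ORIN1001, with a median of 0.70 at percentile 100. Gbp2 was at 2.28, Gbp4 at 2.23 and Cd274, the gene of PD-L1, at 1.31. All 7 MHC class II genes were higher, with a median of 0.33 and the transactivator Ciita at 0.78 (0.68 to 0.88). Of the type I interferon genes 16 of 18 were higher, with a median of 0.32. Inflammatory macrophage genes had 9 of 11 members lower and a median of -0.64, with Nfkbia at -1.02 and Ptgs2 at -0.996, while Nos2 was higher at 1.51. The dissociation stress list, which marks tissue handling as well as activation, was lower beside them, with 9 of 11 members and a median of -0.62. Among lipid-associated genes Spp1 was at -1.04 and Trem2 at -0.69, against Cd36 at 2.16, and the median was -0.22. Of the XBP1s and chaperone genes 15 of 18 were lower, with a median of -0.16, with Herpud1 at -0.85. The hypoxia and glycolysis list had 9 of 12 members higher and a median of 0.16.

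In T cell-like cells all 9 checkpoint and exhaustion genes were higher with ORIN1001, with a median of 0.84 at percentile 100. Lag3 stood at 272 CPM against 70.0 CPM, a log2 ratio of 1.96 (1.82 to 2.10). Havcr2, the gene of TIM-3, was at 2.10 (1.85 to 2.36), and Pdcd1, the gene of PD-1, at 0.98 (0.88 to 1.09). Cytotoxic effectors had 9 of 10 members higher and a median of 0.66, with Prf1 at 2.10 and Ifng at 0.83. Within CD8 T cell-like cells the checkpoint and cytotoxic medians were 0.69 and 0.29, and within regulatory T cell-like cells 0.055 and -0.058. The naive and memory T cell list had 5 of 7 members lower and a median of -0.46, with Klf2 at -1.11. Cholesterol synthesis had all 11 members higher and a median of 0.51, with Idi1 at 0.85 and Fdft1 at 0.68. Type I interferon genes were lower, 17 of 18 with a median of -0.36, though the median was -0.10 without doublet removal. XBP1s and chaperone genes were lower in all 18 members with a median of -0.35, but the medians were -0.07 within CD8 T cell-like and -0.10 within regulatory T cell-like cells.

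The make-up of the T cell-like class differed as well. CD8 T cell-like cells were 43.4% (40.4 to 46.4) of T and NK cells with ORIN1001 and 31.7% (29.2 to 34.3) in vehicle. Regulatory T cell-like cells were 18.0% against 7.93%, and γδ T cell-like cells 6.80% against 19.2%. The largest negative ratios in the T cell-like class, Cd163l1 at -5.25 and Il17a at -2.62, belong to genes of interleukin-17-producing γδ T cells, and 1 γδ subcluster held 5 cells with ORIN1001 and 132 in vehicle. Neutrophil markers in T cell-like cells summed to 654 CPM against 2360 CPM in vehicle and macrophage markers to 98.8 CPM against 230 CPM, beside the lower dissociation stress list at -1.13, inflammatory list at -1.10, PERK-ATF4 list at -0.53, chemokine list at -2.71 and MHC class II list at -2.29. An unnamed subcluster led by the neutrophil genes S100a9 and S100a8 held 66 cells in vehicle and 23 with ORIN1001, and unnamed subclusters together were 12.96% of T and NK cells in vehicle and 11.3% with ORIN1001. Doublet removal took a larger share of the ORIN1001 library than of vehicle. Without it, a subcluster led by S100a8 and S100a9 held 134 vehicle and 123 ORIN1001 cells, a much smaller gap. These counts do not show how much of the lower markers and lists goes with doublet removal.

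**Figure D2:**
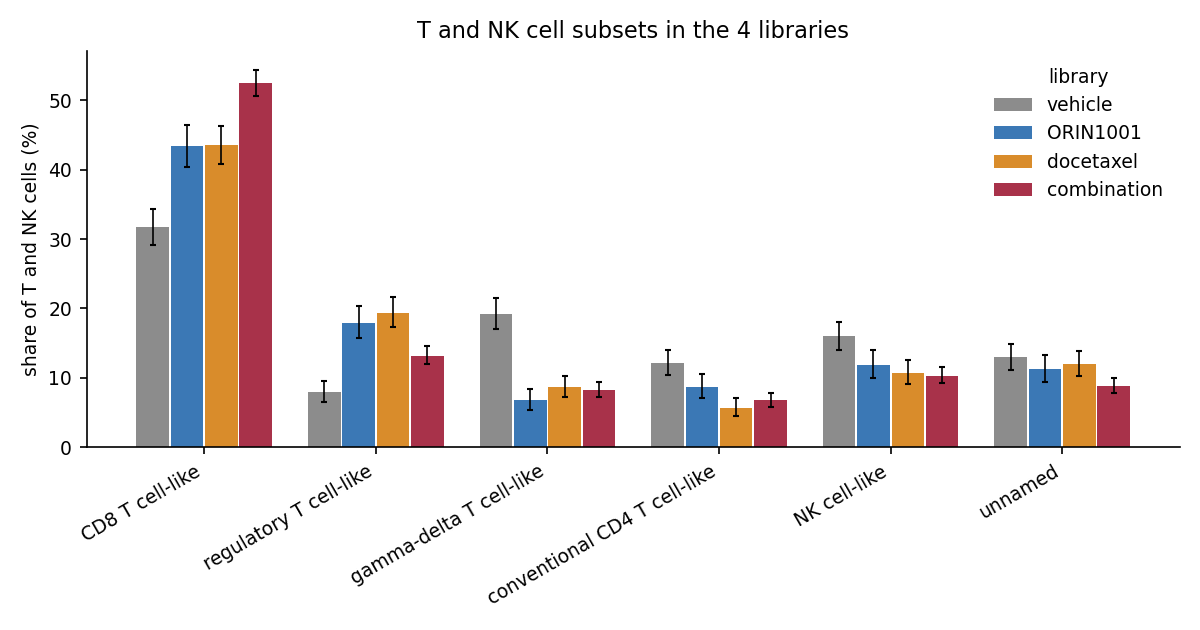
Share of T and NK cells (%) in each subset for the 4 libraries, with exact 95% binomial intervals as error bars and 1 bar per library. The CD8 T cell-like bar is lowest in vehicle at 31.7% and highest in the combination at 52.5%, and the γδ T cell-like bar is highest in vehicle at 19.2%.

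The comparison of docetaxel with vehicle asked what the taxane alone went with. Type I interferon genes were higher in all 3 large classes, hypoxia and glycolysis genes were lower in all 3, and inflammatory and cholesterol synthesis genes were lower in macrophage-like cells. In neutrophil-like cells Ifit3, an interferon-induced antiviral gene, stood at 456 CPM against 155 CPM, a log2 ratio of 1.55 (1.49 to 1.62). Hilpda, a hypoxia-inducible lipid droplet gene, stood at 527 CPM against 1268 CPM, a log2 ratio of -1.27 (-1.30 to -1.23). Monocyte-like, dendritic cell-like and T cell-like cells took larger shares than in vehicle, and macrophage-like cells a smaller one. The monocyte-like gain was much smaller without doublet removal.

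Monocyte-like cells were 6.25% (5.74 to 6.80) of kept cells with docetaxel and 3.40% (3.05 to 3.77) in vehicle, a log2 share ratio of 0.88 (0.68 to 1.08). Without doublet removal the class held 276 of 8343 docetaxel and 299 of 10239 vehicle cells, a much smaller gain. At the lower Leiden resolution it held 343 of 8237 docetaxel and 301 of 10034 vehicle cells, also a smaller gain. Conventional DC-like cells were 3.61% against 1.81%, pDC-like cells 1.74% against 0.847%, and mature DC-like cells 0.971% against 0.249%. T cell-like cells were 14.0% (13.3 to 14.8) against 10.99% (10.4 to 11.6). Macrophage-like cells were 17.5% (16.7 to 18.3) against 22.8%, a log2 share ratio of -0.38 that lay between -0.25 and -0.20 under 5 other settings, 1 of them chosen after seeing the data. The joined macrophage and monocyte class was 23.7% against 26.2%. Neutrophil-like cells were 53.5% (52.4 to 54.6) against 56.0%, a log2 share ratio of -0.07, which became -0.26 when classes were taken per cell from marker means. Within T and NK cells, CD8 T cell-like cells were 43.5% against 31.7%, regulatory T cell-like cells 19.4% against 7.93% and γδ T cell-like cells 8.66% against 19.2%, with 11.99% unnamed. Conventional CD4 T cell-like cells were 5.65% against 12.2%, and turned higher at a subset resolution of 2, with a log2 share ratio of 0.33.

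In neutrophil-like cells all 18 measured type I interferon genes were higher with docetaxel, with a median of 1.20 at percentile 100, but within cluster 10 (1104 and 294 cells) 12 of 18 were lower and the median was -0.067. The other 6 neutrophil-like clusters had medians from 0.19 to 1.496, all higher with docetaxel. Cluster 9, whose leading genes included Ifit1, Ifit2 and Rsad2, held 455 docetaxel and 163 vehicle cells, which the cluster 10 median leaves out. In the whole class Ifit2 was at 1.41 (1.36 to 1.47). All 15 interferon-γ and MHC class I genes were higher too, with a median of 0.87, Cxcl10 at 1.41 and Gbp4 at 2.21, while within cluster 10, a neutrophil-like cluster filled more by this library, 9 of 15 were higher and the median was 0.11, and it reached 0.79 in the other clusters. Hypoxia and glycolysis genes were lower in all 12 members, with a median of -0.74 at percentile 0, Bnip3 at -0.98 and Adm at -1.40, and medians from -0.90 to -0.30 within single clusters. The largest ratios were those of Ngp at -6.81 (-7.77 to -6.01) and Camp at -4.34 (-4.86 to -3.86), granule genes of immature neutrophils, and of Cish, a cytokine-inducible inhibitor of cytokine signalling, at 2.96 (2.68 to 3.24). Of 4406 neutrophil-like cells with docetaxel and 5620 in vehicle, the cluster led by Ngp and Camp held 175 and 343. That gap is far smaller than the Ngp and Camp ratios. The cluster led by Ciart, Ccdc126 and Hilpda held 725 and 1763. Tubulins were higher in all 8 members with a median of 0.34 at percentile 97.2, within the random range, with Tubb4b at 0.69. The tubulin median with docetaxel was 0.26 in macrophage-like cells, but -0.34 in T cell-like and -0.54 in pDC-like cells. The heat shock genes Hspa1a and Hspa1b were at -1.73 and -1.37.

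Macrophage-like cells had 17 of 18 type I interferon genes higher with docetaxel, with a median of 0.80, Usp18 at 1.16 and Oasl2 at 1.12. Interferon-γ and MHC class I genes had 14 of 15 members higher and a median of 0.52, whereas MHC class II genes were lower in all 7 members with a median of -0.20. Inflammatory genes had 9 of 12 members lower and a median of -0.70, with Tnf at 71.9 CPM against 221 CPM and Ptgs2 at -1.61. The dissociation stress list was lower with them, 10 of 11 members with a median of -0.95, and neutrophil markers in these cells had a median of -1.28. Cholesterol synthesis was lower in all 11 members, with a median of -0.60 and Sqle at -0.89. Hypoxia and glycolysis genes were lower in all 12 members, with a median of -0.40 and Vegfa at -0.98. XBP1s and chaperone genes had 16 of 18 members higher and a median of 0.28 at percentile 100, with Creld2 at 0.50. Lpl, the lipoprotein lipase gene, was at 1.24 (1.14 to 1.35), and 9 of 11 lipid-associated genes were higher. Proliferation genes were higher in all 14 members with a median of 0.27.

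In T cell-like cells all 18 measured type I interferon genes were higher with docetaxel, with a median of 0.88, Ifit3 at 1.12 and Oas1a at 1.09. All 9 checkpoint genes were higher, with a median of 0.94, Lag3 at 1.41 (1.26 to 1.56), Ctla4 at 1.29 (1.22 to 1.37) and Pdcd1 at 1.27 (1.17 to 1.37). Cytotoxic effectors were higher in all 10 members with a median of 0.62, while the medians were 0.32 within CD8 T cell-like and -0.26 within regulatory T cell-like cells. The checkpoint medians within these subsets were 0.67 and 0.16. Xcl1, which encodes a chemokine that attracts cross-presenting dendritic cells, stood at 637 CPM against 114 CPM, and Ccl1 at 287 CPM against 21.4 CPM. Naive and memory genes had 6 of 7 members lower and a median of -0.32. Cholesterol synthesis had 10 of 11 members lower and a median of -0.50. XBP1s and chaperone genes were lower in all 18 members with a median of -0.19, but the medians were -0.06 within CD8 T cell-like and 0.11 within regulatory T cell-like cells. Neutrophil markers in T cell-like cells had a median of -1.81, beside the hypoxia list at -0.43, the PERK-ATF4 list at -0.57 and the dissociation stress list at -0.69. The hypoxia median was -0.16 at percentile 4.63 within CD8 T cell-like cells. Within regulatory T cell-like cells it was -0.15 at percentile 6.70. Both lay within the random range.

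The comparison of the combination with vehicle asked what both drugs together went with. The combination library held the largest T cell-like share of the 4 libraries, with higher Lag3, Havcr2 and Prf1 in the T cell-like class, and the smallest neutrophil-like share. Neutrophil-like cells carried higher interferon-γ-response genes and lower hypoxia genes, and macrophage-like cells lower inflammatory genes. Tgtp1, an interferon-inducible GTPase, stood at 198 CPM in neutrophil-like cells against 4.88 CPM, a log2 ratio of 5.34 (5.04 to 5.65). Hilpda stood at 42.5 CPM in the same cells against 1268 CPM, a log2 ratio of -4.90 (-5.05 to -4.75).

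T cell-like cells were 27.7% (26.8 to 28.7) of kept cells in the combination library and 10.99% (10.4 to 11.6) in vehicle, a log2 share ratio of 1.33 (1.23 to 1.44). Outside the neutrophil-like class they were 45.5% against 24.99%. CD8 T cell-like cells alone were 16.3% (15.5 to 17.1) of kept cells against 4.15% (3.76 to 4.55), and 52.5% against 31.7% of T and NK cells. Regulatory T cell-like cells were 13.2% of T and NK cells against 7.93%, γδ T cell-like cells 8.30% against 19.2%, and unnamed cells 8.89% against 12.96%. Neutrophil-like cells were 39.1% (38.0 to 40.1) of kept cells against 56.0%, a log2 share ratio of -0.52 (-0.58 to -0.46). Macrophage-like cells were 14.7% (14.0 to 15.5) against 22.8%, a log2 share ratio of -0.63 that was -0.31 without doublet removal, and the joined macrophage and monocyte class was 21.4% against 26.2%. Monocyte-like cells were 6.68% against 3.40%, but without doublet removal the class held 277 of 8945 combination and 299 of 10239 vehicle cells, a much smaller gain. Conventional DC-like cells were 4.13% against 1.81%, pDC-like cells 2.62% against 0.847% and NK cell-like cells 3.27% against 2.08%. Outside the neutrophil-like class these last gains were smaller, and that of NK cell-like cells, from 287 and 209 cells, was small.

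Different clusters filled the neutrophil-like class in these 2 libraries. The cluster led by Ciart, Ccdc126 and Hilpda held 69 cells of the combination and 1763 of vehicle, and another, cluster 6, held 60 and 1488. Cluster 10, whose leading genes included Gbp5 and Il1rn, held 1962 and 294. In the T cell-like class a cluster led by Penk, Ccl1 and Pdcd1 held 724 and 104 cells. A CD8 subcluster led by Havcr2, Lag3 and Adgrg1 held 414 cells of the combination, 74 of ORIN1001, 40 of docetaxel and 5 of vehicle.

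In neutrophil-like cells all 15 interferon-γ and MHC class I genes were higher in the combination library, with a median of 1.96 at percentile 100. Gbp4 was at 4.72 (4.52 to 4.92), Nlrc5 at 3.57 (3.36 to 3.78) and Gbp2 at 2.68 (2.62 to 2.73). Type I interferon genes were higher in all 18 members with a median of 1.37, but within cluster 10, which held most of the combination's neutrophil-like cells, 12 of 18 were lower and the median was -0.42. It lay between 0.28 and 1.74 in the other 6 neutrophil-like clusters. Cluster 9, whose leading genes included Ifit1, Ifit2 and Rsad2, held 347 combination and 163 vehicle cells. Because clusters were drawn from the same expression values, the cluster 10 median leaves those cells out and does not speak against the higher list in the class. The dsRNA sensing and pyroptosis list had 12 of 14 members higher and a median of 0.64, with Zbp1 at 2.30 and Casp1 at 1.40. Hypoxia and glycolysis genes were lower in all 12 members, with a median of -2.001 at percentile 0, Adm at -4.05, Bnip3 at -2.61 and Vegfa at -2.18. Within the 7 neutrophil-like clusters the hypoxia median ran from -1.78 to -0.42 and the interferon-γ median from 0.48 to 1.99, with -1.17 and 0.99 in cluster 10 and -1.01 and 1.69 in cluster 11. Ngp was at -6.96 (-8.28 to -5.92) and Prok2, which encodes prokineticin 2, at -5.84 (-6.42 to -5.32). Edn1, the endothelin 1 gene, was at 5.004 (4.50 to 5.55), Nos2 at -3.63 and Cdkn1a at -1.35.

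Markers of other classes were higher in these neutrophil-like cells too, T cell markers with a median of 1.81 and macrophage markers with a median of 0.85. Beside them stood medians of 1.29 for MHC class II genes, 1.68 for cytotoxic effectors, 2.22 for checkpoint genes and 0.76 for the alternatively activated list. Some of these genes, such as H2-Eb1, Nkg7 and Ccl5, stood at about 1% or less of their level in the class where they were highest. Others, such as Cd274 at 0.76 (0.71 to 0.81), Entpd1, Ccl3 and Ccl4, were highest in neutrophil-like cells. Tubulins had 7 of 8 members higher and a median of 0.66. Of the XBP1s and chaperone genes 13 of 18 were lower, with Dnajb9 at -0.93 and a median of -0.17 at percentile 3.43, within the random range. The list's median was 0.09 in macrophage-like and -0.20 in T cell-like cells. Within CD8 T cell-like and regulatory T cell-like cells it was 0.07 and 0.14. RIDD substrates in neutrophil-like cells had a median of -0.36. Scaling by TMM factors shifted the median of all 2732 genes in neutrophil-like cells from 0.03 to -0.10 in this contrast, from 0.10 to -0.05 for docetaxel to vehicle and from -0.03 to 0.07 for ORIN1001 to vehicle.

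Macrophage-like cells had all 15 interferon-γ and MHC class I genes higher in the combination library, with a median of 1.06 and Cxcl9 at 3.15 (3.05 to 3.26). Iigp1, an interferon-inducible GTPase, was at 4.44 (4.15 to 4.74). All 7 MHC class II genes were higher, with a median of 0.50 and H2-Eb1 at 0.53. Inflammatory genes had 9 of 11 members lower and a median of -1.28, with Il1b at 757 CPM against 1838 CPM, Tnf at -1.84 and Il1a at -1.90. Cxcl1, a chemokine that attracts neutrophils, stood at 14.0 CPM against 137 CPM, a log2 ratio of -3.30 (-3.45 to -3.15), while Ccl8 was higher at 2.12, and the chemokine list had a median of -0.59. Hypoxia and glycolysis genes were lower in all 12 members with a median of -1.05. Alternatively activated genes had 8 of 11 members lower and a median of -0.88, with Ccl24 at -2.42 but Arg1 at 1.33 (1.27 to 1.40). Neutrophil markers in macrophage-like cells summed to 168 CPM against 947 CPM, and the dissociation stress list had a median of -1.13, beside these lower inflammatory and hypoxia genes. Cholesterol synthesis had 10 of 11 members lower and a median of -0.39.

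In T cell-like cells all 9 checkpoint and exhaustion genes were higher in the combination library, with a median of 1.40 at percentile 100. Lag3 stood at 469 CPM against 70.0 CPM, a log2 ratio of 2.75 (2.62 to 2.88), Havcr2 was at 2.42 (2.18 to 2.66) and Pdcd1 at 1.80 (1.71 to 1.89). Within CD8 T cell-like cells the checkpoint median was 1.12 and the cytotoxic median 0.37. Cytotoxic effectors had 9 of 10 members higher and a median of 0.90, with Prf1 at 2.78 (2.59 to 2.98) and Nkg7 at 1.25. Adgrg1, a receptor gene of cytotoxic lymphocytes, was at 2.98 (2.59 to 3.39). Naive and memory genes were lower in all 7 members with a median of -0.41, with Klf2 at -1.83 and Tcf7 at -0.68. Lta, the lymphotoxin α gene, was at -3.15 (-3.38 to -2.91). Cholesterol synthesis had 10 of 11 members lower and a median of -0.56. Hypoxia genes were lower in all 11 measured members with a median of -1.03, but -0.21 within CD8 T cell-like and -0.33 within regulatory T cell-like cells, beside neutrophil markers in the class with a median of -3.04 and the dissociation stress list at -1.42. Proliferation genes had a median of -0.04 in the class but -0.44 at percentile 0 within CD8 T cell-like cells, with 12 of 14 lower. For p53 targets the median was 0.14.

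**Figure D3:**
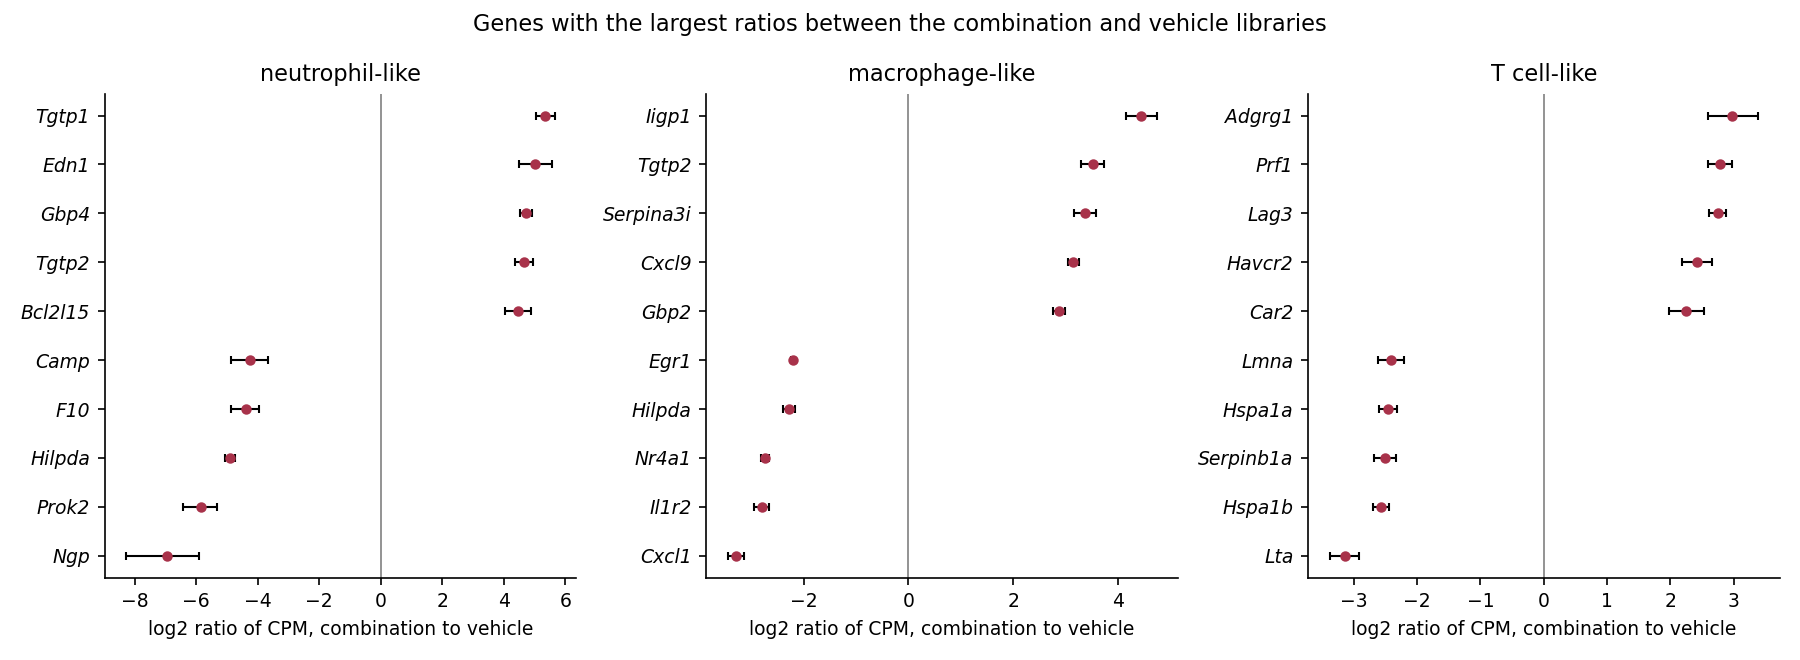
Log2 ratio of CPM between the combination and vehicle libraries for the 5 genes with the largest positive and the 5 with the largest negative ratios in each of 3 cell classes, with points as ratios and bars as 95% Poisson intervals. Tgtp1 at 5.34 and Ngp at -6.96 mark the ends in neutrophil-like cells, Iigp1 at 4.44 and Cxcl1 at -3.30 in macrophage-like cells, and Adgrg1 at 2.98 and Lta at -3.15 in T cell-like cells.

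The comparison of the combination with docetaxel asked what adding ORIN1001 to the taxane went with. With ORIN1001 added, interferon-γ-response genes were higher again in neutrophil-like and macrophage-like cells, hypoxia genes were lower, and Prf1, Havcr2 and Lag3 were higher in T cell-like cells. Type I interferon genes were lower in T cell-like cells. In neutrophil-like cells Gbp4 stood at 291 CPM against 51.3 CPM, a log2 ratio of 2.502 (2.38 to 2.63). T cell-like cells were 27.7% of kept cells against 14.0%, a log2 share ratio of 0.98 (0.88 to 1.08), and neutrophil-like cells 39.1% against 53.5%, a log2 share ratio of -0.45 (-0.52 to -0.39).

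CD8 T cell-like cells were 16.3% of kept cells in the combination library against 6.84% (6.30 to 7.40) with docetaxel, and 52.5% of T and NK cells against 43.5%. Regulatory T cell-like cells were 13.2% (11.97 to 14.6) of T and NK cells against 19.4% (17.3 to 21.7). NK cell-like cells were 3.27% of kept cells against 1.65%, and pDC-like cells 2.62% against 1.74%. Mature DC-like cells were 0.364% against 0.971%, from 32 and 80 cells. Macrophage-like cells were 14.7% against 17.5%, a log2 share ratio of -0.25 (-0.36 to -0.14) that was -0.10 without doublet removal.

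In neutrophil-like cells all 15 interferon-γ and MHC class I genes were higher in the combination than with docetaxel, with a median of 1.13 at percentile 100, Nlrc5 at 1.58 and Gbp2 at 1.22. Cxcl9 was at 2.51 (2.28 to 2.76), at 11% of its level in the class where it was highest. Of the type I interferon genes 12 of 18 were higher, with a median of 0.12, but 14 of 18 were lower within cluster 10 and the median was -0.30. It was -0.28 in the cluster led by Ciart, Ccdc126 and Hilpda and between 0.0082 and 0.60 in the other 5. Hypoxia and glycolysis genes were lower in all 12 members, with a median of -1.35 at percentile 0, Hilpda at -3.63 (-3.79 to -3.48) and Hk2 at -1.48, and the cluster led by Ciart, Ccdc126 and Hilpda held 69 and 725 cells. Within single neutrophil-like clusters the hypoxia median was nearer 0, from -1.06 to -0.14, and the interferon-γ median ran from 0.33 to 1.25. XBP1s and chaperone genes had 16 of 18 members lower and a median of -0.22, with Dnajb9 at -0.59 and Creld2 at -0.48. MHC class II genes were higher in all 7 members with a median of 0.90, beside macrophage markers with a median of 0.37 and T cell markers with a median of 1.10. Cdkn1a was at -1.11 and Bax at -0.75 among p53 targets, whose median was -0.14.

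Macrophage-like cells had all 15 interferon-γ and MHC class I genes higher than with docetaxel, with a median of 0.81, and Cxcl9 stood at 185 CPM against 45.4 CPM. All 7 MHC class II genes were higher, with a median of 0.68 and Ciita at 1.13 (1.04 to 1.23). Saa3, an acute phase gene, was at 3.86 (3.71 to 4.01). Hypoxia genes were lower in all 12 members with a median of -0.50. XBP1s and chaperone genes had 16 of 18 members lower and a median of -0.20 at percentile 0.030, with Herpud1 at -0.56. Lipid-associated genes had 9 of 11 members lower and a median of -0.53, with Spp1 at -1.08 and Cd9 at -0.83 but Cd36 at 1.09. Mmp12, the macrophage elastase gene, was at -2.01 (-2.14 to -1.88). Alternatively activated genes had 9 of 11 members lower and a median of -0.26, with Retnla at -6.80 (-8.68 to -5.43) but Arg1 at 1.07. Inflammatory genes had 8 of 12 members lower and a median of -0.24, with neutrophil markers at a median of -0.65. Cholesterol synthesis was higher in all 11 members with a median of 0.22.

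Checkpoint genes in T cell-like cells had 6 of 9 members higher than with docetaxel and a median of 0.42. Prf1 stood at 218 CPM against 71.2 CPM, a log2 ratio of 1.61 (1.48 to 1.74), Havcr2 was at 1.48 (1.31 to 1.66), Lag3 at 1.34 (1.26 to 1.42) and Entpd1, the gene of CD39, at 1.04. Cytotoxic effectors had 7 of 10 members higher and a median of 0.34, with Gzma lower at -0.86, and the median was 0.028 within CD8 T cell-like cells. Type I interferon genes were lower in all 18 members, with a median of -0.70 at percentile 0, Rsad2 at -1.13 and Ifit3 at -1.07, and a median of -1.04 within CD8 T cell-like cells. Xcl1 was at -1.83 and Ccl1 at -1.71. The XBP1s and chaperone list had 10 of 18 members lower and a median of -0.01, which was 0.01 with TMM factors. PERK-ATF4 genes had a median of -0.60 and the dissociation stress list a median of -0.63, beside neutrophil markers with a median of -1.20.

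**Figure D4:**
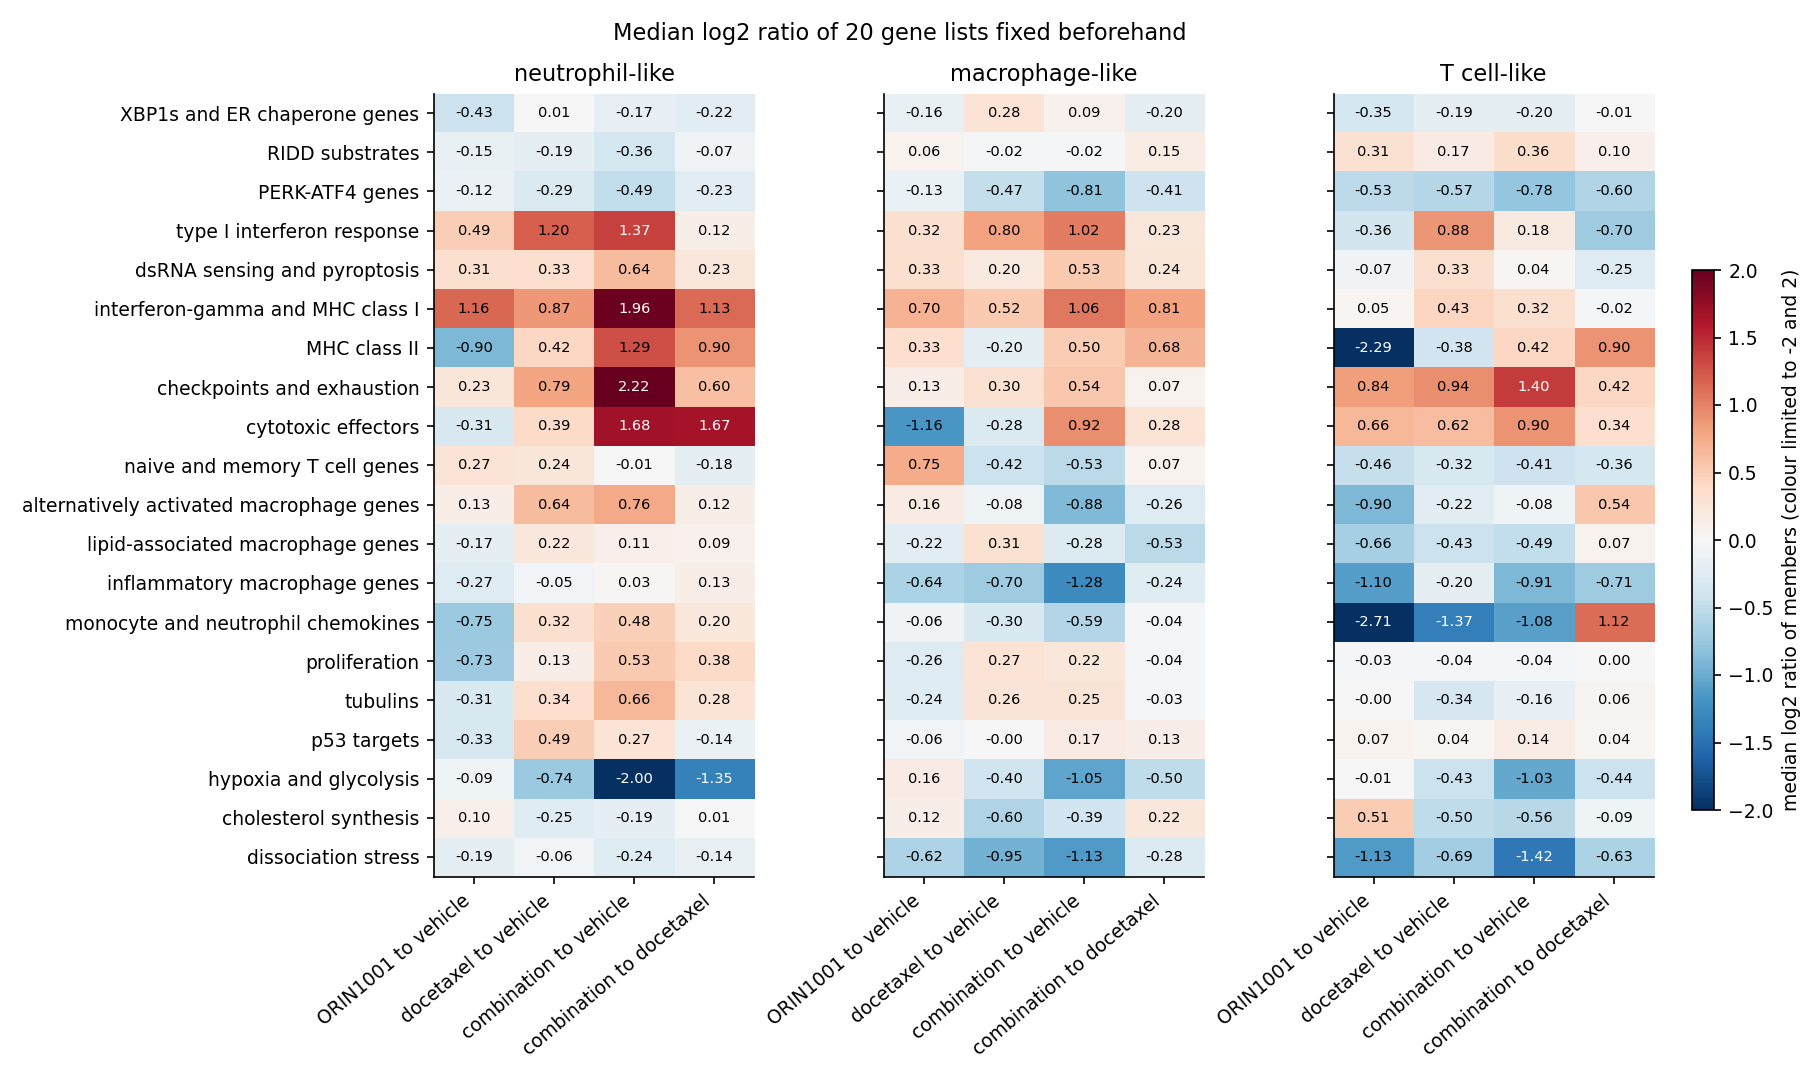
Median log2 ratio of the members of each of 20 gene lists (vertical) for 4 contrasts (horizontal) in 3 cell classes, written in each field and coloured from -2 to 2; lists named for another class, such as MHC class II genes in T cell-like cells at -2.29, hold genes far below their level in their own class there. The interferon-γ and MHC class I field of neutrophil-like cells runs from 0.87 to 1.96 and the hypoxia field of the combination to vehicle from -2.001 in neutrophil-like to -1.03 in T cell-like cells.

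Across genes, the effect of ORIN1001 alone was set against its effect on top of docetaxel, a pair of contrasts that share no library. Pearson's r was 0.388 and Spearman's rho 0.351 over 2732 genes in neutrophil-like cells, 0.513 and 0.432 over 2921 genes in macrophage-like cells, and 0.352 and 0.294 over 3403 genes in T cell-like cells. For docetaxel to vehicle against combination to ORIN1001 the values were 0.853 and 0.833, 0.678 and 0.703, and 0.266 and 0.317 in the same classes, and r was 0.473 in T cell-like cells over 755 genes of at least 200 CPM. These 6 relations are across genes, genes are not independent replicates, and no p-value was computed. For reference, on mm10 Gbp4 (ENSMUSG00000079363) lies on chromosome 5, 105115767 to 105139586, Tgtp1 (ENSMUSG00000078922) on chromosome 11, 48985327 to 48994172, and Hilpda (ENSMUSG00000043421) on chromosome 6, 29272488 to 29275446. Cxcl9 (ENSMUSG00000029417) lies on chromosome 5, 92321347 to 92328079, Lag3 (ENSMUSG00000030124) on chromosome 6, 124904361 to 124911705, Havcr2 (ENSMUSG00000020399) on chromosome 11, 46454935 to 46481255, and Prf1 (ENSMUSG00000037202) on chromosome 10, 61297833 to 61304680.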

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

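The tests chosen after the result was seen were the equal doublet rule, the T cell receptor gene share, and the tests that set the rise of interferon-γ genes against free RNA of other classes. The shares and lists given below without and with the other drug were picked out because the effect of 1 drug had opposite directions. The CD8 subcluster and the hypoxia and interferon-γ genes of neutrophil-like cells, which come after them, were not picked by this rule. In each case the groups held single libraries and the difference was not tested.

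For ORIN1001, the log2 share ratio without docetaxel and with it was -0.44 and 0.99 for NK cell-like cells, a difference of 1.43, and 0.33 and -0.45 for neutrophil-like cells, a difference of -0.78. It was -1.15 and 0.59 for pDC-like cells, a difference of 1.75, and -1.99 and 1.38 for epithelial or tumour cell-like cells, a difference of 3.37 that rests on 30 to 147 cells per library in a CD45 sort. Regulatory T cell-like cells as a share of T and NK cells stood at 1.18 and -0.55, a difference of -1.73. For docetaxel, the macrophage-like share stood at -0.38 without ORIN1001 and 0.34 with it, a difference of 0.717. By the same differences, the docetaxel ratios without and with ORIN1001 were also opposite for NK cell-like (-0.34 and 1.09), epithelial or tumour cell-like (-1.63 and 1.74) and regulatory T cell-like shares (1.29 and -0.44). Shares of kept cells also move with the size of the neutrophil-like class. Outside that class, the macrophage-like share was lower with docetaxel both without and with ORIN1001. It rested on 2284 vehicle, 949 ORIN1001, 1440 docetaxel and 1292 combination cells. The NK cell-like share outside it was not lower with ORIN1001, either without or with docetaxel, from 209, 125, 136 and 287 cells. Neither effect had opposite directions there. The difference was not tested in any of these shares.

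Among gene lists, the ORIN1001 medians in neutrophil-like cells without and with docetaxel were -0.90 and 0.90 for MHC class II genes (difference 1.80), beside macrophage markers at -1.14 and 0.37. They were -0.75 and 0.20 for chemokines (0.95), -0.73 and 0.38 for proliferation (1.11) and -0.31 and 0.28 for tubulins (0.59), and the proliferation median with docetaxel turned to -0.01 in thinned cells. In macrophage-like cells they were -1.16 and 0.28 for cytotoxic effectors (1.43), beside NK cell markers at -1.13 and 0.84, and 0.16 and -0.50 for hypoxia and glycolysis (-0.66). In T cell-like cells they were -2.29 and 0.90 for MHC class II genes (3.19) and -2.71 and 1.12 for chemokines (3.82), beside macrophage markers at -1.14 and 0.07. Within CD8 T cell-like cells the medians were -0.89 and -0.07 for MHC class II genes, which is not an opposite direction, and -0.13 and 0.75 for chemokines. For docetaxel without and with ORIN1001 the T cell-like medians were -0.38 and 2.71 for MHC class II genes and -1.37 and 2.03 for chemokines. Within CD8 T cell-like cells these docetaxel medians were 0.39 and 1.36, and 0.33 and 1.08, so neither list had opposite directions there. An unnamed subcluster of T and NK cells led by H2-Aa, Cd74 and H2-Eb1 held 15 vehicle, 3 ORIN1001, 6 docetaxel and 31 combination cells. Without doublet removal, a subcluster led by H2-Aa and Cd74 held 25, 8, 6 and 32 in the same order. The doublet rule removed the largest share from the ORIN1001 library, and 1 rate for every library was applied to shares only. Without doublet removal, 9 of 240 list medians moved and 0 reversed, but combination to ORIN1001 was not among them. For docetaxel, XBP1s and chaperone genes in T cell-like cells stood at -0.19 without ORIN1001 and 0.17 with it (0.36), while the medians were -0.06 and 0.25 within CD8 T cell-like and 0.11 and 0.20 within regulatory T cell-like cells, the latter in the same direction. The difference was not tested in any of these lists.

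The neutrophil-like share was above vehicle with ORIN1001 and, with both drugs, below docetaxel. Unequal doublet removal would have carried the pattern only if 1 rule for every library ended it, and under that rule the log2 share ratios were 0.304 and -0.42, which argues against it. Chance differences between animals, tumours or sorts stay open, because each group held 1 library. An interaction of the drugs on neutrophils is a hypothesis that may be raised here, and it cannot be told apart from those chance differences.

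A CD8 subcluster led by Havcr2, Lag3 and Adgrg1 came mostly from the combination library. Deeper cells could show more of these genes. The checkpoint median in CD8 T cell-like cells was 1.42 after thinning to 1000 UMIs and 1.12 before. The higher list therefore did not rest on deeper cells weighing more in the sum. Subclusters were not made again from thinned cells, so whether depth shaped this subcluster stays open. A single expanded clone could also fill the subcluster, but its commonest Trbv gene, Trbv13-2, led in 23.3% (19.3 to 27.7) of 412 cells, which argues against 1 clone. An effect of the drugs on exhausted-like CD8 T cells stays open as a hypothesis, as do differences between single tumours.

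In neutrophil-like cells, hypoxia genes were lower and interferon-γ genes higher in the combination library than in vehicle. Different clusters filled the class. The hypoxia median was -2.001 in the class, but -1.01 within cluster 11 and between -1.78 and -0.42 over the single clusters. The mix of clusters may account for part of the difference, and how much stays open. Macrophage markers were higher too, with a median of 0.85, but stood at 2.65% (2.13 to 9.22) of their own level, while the interferon-γ genes rose by 275% (89.7 to 803) of theirs in macrophage-like cells, which argues against macrophage RNA as the source. Set against the other class where each gene was highest, the rise was 77.9% (47.7 to 119), and RNA of other classes may have added to it, since monocyte markers, some of them higher in neutrophil-like than in monocyte-like cells, stood at 9.46% with an upper limit of 364%. A response of neutrophils to both drugs is a hypothesis that remains beside these.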

How the results depend on the processing

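Of the alternatives, 1 doublet rate for every library and the joined macrophage and monocyte class were chosen after seeing the data, as were the tests built on them, and the others were planned. With no replicates, nothing could be left out in turn. Of 356 values for 60 share ratios, 306 were the same within the interval, 46 moved and 4 reversed. Of 1433 values for 240 list medians, 1407 were the same, 19 moved and 7 reversed. Of 600 values for 120 named genes, 436 were the same, 164 moved and 0 reversed. Of 12 values for 6 correlations, 11 were the same, and Pearson's r in T cell-like cells for the docetaxel pair moved to 0.473 at 200 CPM. For every change given here the cause was not tested.

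With classes taken per cell from marker means, the T cell-like log2 share ratio was 0.24 for ORIN1001, 0.48 for docetaxel and 1.46 for the combination, each to vehicle. The neutrophil-like ratio was 0.385, -0.26 and -0.64 in the same order, and -0.385 for the combination to docetaxel. The monocyte-like ratio for ORIN1001 to vehicle reversed to 0.22. Without doublet removal, 299 of 10239 vehicle, 276 of 8343 docetaxel and 277 of 8945 combination cells were monocyte-like. The monocyte-like gains with docetaxel and with the combination were thus much smaller than reported. The macrophage-like ratio for docetaxel to vehicle, -0.38 as reported, was -0.235 at resolution 0.5, -0.25 at resolution 2, -0.20 without doublet removal, -0.22 with classes per cell and -0.205 with 1 doublet rate. For the combination to vehicle, -0.63 as reported, it was -0.42, -0.49, -0.31, -0.40 and -0.36 in the same order, and for the combination to docetaxel -0.10 without doublet removal. Conventional CD4 T cell-like shares reversed at subset resolution 2, to 0.70 for ORIN1001, 0.33 for docetaxel and 0.585 for the combination.

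The interferon-γ median in neutrophil-like cells, docetaxel to vehicle, was 0.72 with TMM factors. In thinned cells, medians reversed for proliferation in neutrophil-like cells, combination to docetaxel, at -0.015, for proliferation in macrophage-like cells, ORIN1001 to vehicle, at 0.053, and for cytotoxic effectors in macrophage-like cells, combination to vehicle, at -0.046. The type I interferon median in T cell-like cells was -0.10 for ORIN1001 without doublet removal and 0.965 for docetaxel with the mean of each cell's CPM. In T cell-like cells thinning also reversed the lipid-associated and inflammatory lists for docetaxel, to 0.082 and 0.13, and chemokines for the combination to vehicle, to 0.83, or 0.086 with the mean of each cell's CPM.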

Other observations

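The T cell receptor tests in this part were chosen after the result was seen, and the lists described here were picked from planned values after these were seen. Outside the 3 large classes, type I interferon genes were higher with docetaxel than with vehicle in every class measured, with medians of 0.67 in monocyte-like, 0.70 in conventional DC-like, 1.04 in pDC-like and 0.79 in NK cell-like cells. With ORIN1001 they were lower in monocyte-like cells at -0.22, conventional DC-like cells at -0.42 and NK cell-like cells at -0.45, and 0.02 in pDC-like cells. Regulatory T cell-like and CD8 T cell-like cells, which lie within the T cell-like class, stood at 0.58 and 0.58 with docetaxel and -0.55 and -1.02 with ORIN1001.

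Cholesterol synthesis genes were lower with docetaxel in these classes too, with medians of -0.63 in monocyte-like, -0.45 in conventional DC-like, -1.05 in pDC-like and -0.89 in NK cell-like cells. With ORIN1001 they were at 0.47, 0.26, -0.77 and 0.71 in the same order, and in the combination to vehicle at -0.83, -0.61, -1.44 and -0.50. All pDC-like values with ORIN1001 rest on only 31 cells, against 85 in vehicle. XBP1s and chaperone genes with ORIN1001 were at -0.27 in pDC-like and -0.16 in conventional DC-like cells, and at -0.03 in monocyte-like and -0.05 in NK cell-like cells. With docetaxel all 18 were higher in monocyte-like cells, with a median of 0.28. Proliferation genes in NK cell-like cells were lower in all 14 members with docetaxel, with a median of -0.65, and in all 14 with the combination, with a median of -1.06. A cycling NK cell-like subcluster led by histone genes held 22 vehicle, 11 ORIN1001, 8 docetaxel and 6 combination cells. At a subset resolution of 2 a subcluster with the same counts was named γδ T cell-like, so its name is uncertain.

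In the docetaxel library, 71.8% (55.1 to 85.0) of the 39 cells of the Havcr2-led CD8 subcluster with a Trbv UMI had Trbv13-1 as their leading Trbv gene, against 20.7% of 503 other CD8 T cell-like cells. In the ORIN1001 library the commonest in that subcluster was Trbv13-3, in 17.6% of 74 cells. No paired T cell receptor sequences were analysed here, so these values do not establish clones.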
